A study of Mus musculus with 4 samples.

How the data were processed

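RNA-seq was done on colon tissue of germ-free C57BL/6 mice in 4 libraries, 1 each for untreated mice and for mice gavaged with PBS, E. coli or L. rhamnosus GG. Per the labels' protocols, tissue was frozen in TRIzol, RNA was cleaned on columns with DNase treatment, and libraries were made with the Illumina TruSeq RNA v2 kit. Per the submitters' processing notes, TopHat2 and HOMER were used with the mouse build mm9; their versions and the role of each are not given in the sources used here. The authors deposited 1 table of expected counts with 24016 rows, 1 per gene symbol, each with a RefSeq accession and mm9 coordinates, which are printed as listed. The counts rise in steps of 0.5, a unit per the file itself whose origin is not given in the sources used here, and were rounded to whole numbers before use. Of the rows, 20420 carry protein-coding (NM) and 3596 non-coding (NR) accessions, 390 are listed with several copies in the genome, and 4749 are 0 in all libraries. Reads of near-identical genes, such as the beta-globin genes Hbb-bs and Hbb-b1, cannot be assigned with certainty. Whether counting used strand is not given in the sources used here.

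Total counts were 27220697 (untreated), 16289580.0 (PBS), 29368008 (E. coli) and 29899371 (LGG). Trimmed mean of M-values (TMM) factors from edgeR 4.0.16 in R 4.3.3 were 1.05, 0.985, 0.989 and 0.979. Counts scaled to library size (CPM) and log2 ratios were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with a prior of 0.5 counts scaled to library size; figures were drawn with matplotlib 3.10.9. For each ratio a 95% counting interval was taken from the exact conditional binomial distribution (Clopper-Pearson) of the 2 counts. A gene was past the size rule when its log2 ratio was at least 1 in size, the interval excluded 0 and its mean CPM over the 4 libraries was at least 1, which 14450 genes reached. PCR reads without molecular identifiers are not independent molecules, so intervals and the floor of 3 counts for a 0 cover counting error only. No test between conditions was made and no p-value is given, because each group has 1 library; the rule describes these libraries and not the conditions.

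The comparisons were PBS against untreated, LGG against PBS, E. coli against PBS and LGG against E. coli; both bacteria were also set against the untreated library. In all, 38 gene lists for stress responses, metabolism, colon cell types and other tissues were fixed before the data were examined, as were the comparisons, the size rule and the rule for naming genes. Each list was summarised by the median log2 ratio of its members with a mean CPM of at least 1, with a counting interval from 1000 Poisson resamplings and the central 95% of 10000 random lists of the same size matched on mean expression in 20 bins. This gave 152 list medians over the 4 comparisons. In PBS against untreated 21 of the 38 lists fell outside their random range, in LGG against PBS 17, in E. coli against PBS 12 and in LGG against E. coli 23, where 1.9 would by chance if genes were independent, which genes of a list are not. Some lists share members: the acinar list shares 1 gene (Zg16) with the goblet list, and the proximal list shares 5 genes with the colonocyte list.

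Named genes followed a rule. It took Nfe2l2, Keap1, Nqo1, Hmox1, Gclc, Gclm, Txnrd1 and Srxn1 in every comparison. For LGG and E. coli against PBS it took up to 10 higher and 10 lower genes past the size rule against PBS and, in the same direction, against the untreated library, ranked by the interval bound nearest 0. For the other comparisons it took 10 higher and 10 lower genes by that bound. In each list discussed it took up to 4 members past the rule with the largest ratios, or the 2 most abundant members where none passed. Non-coding rows, predicted genes, histones and immunoglobulin variable segments were left out of the ranked parts. Some genes that the rule names are not reported. Genes outside this rule are said to be chosen after their values were seen.

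The correlation of LGG and E. coli ratios was set beside 100 simulations of counting noise with a shared PBS library and beside separate controls. The overlap of the genes past the rule was set beside 100 such simulations, added after seeing the data. On simulated counts for 14450 genes, with 100 genes changed at each of 2 sizes, the rule recovered 95% of genes at a log2 change of 1.25 and 100% at 2 in LGG against PBS, with 13 unchanged genes called. In PBS against untreated it recovered 89% and 100%, in E. coli against PBS 92% and 98%, and in LGG against E. coli 96% and 100%, with 10, 8 and 2 unchanged genes called. Of 20 simulated lists of 30 genes raised by 0.3, 20 fell outside the random range, and of 20 unchanged lists 1 did. Alternatives were size factors from DESeq2 1.42.0, library totals and upper-quartile factors in place of TMM, no expression filter or a mean CPM of at least 5, a prior of 5 counts, a 1.5-fold threshold, and the untreated library as control. TMM factors without Rn45s, and counts without genes of the acinar, adipocyte, mesothelium and blood lists, were added after seeing the data. A choice between transcripts of a gene did not apply, since each symbol has 1 row.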

Results

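RNA from the colon of germ-free C57BL/6 mice aged 7 weeks was profiled by RNA sequencing in 4 libraries, 1 for each of 4 conditions. Mice were left untreated, or were gavaged with phosphate-buffered saline (PBS), with Escherichia coli, or with Lactobacillus rhamnosus GG (LGG), a probiotic strain. Colon pieces of 4 cm were taken 4 h after gavage. The labels give 4 mice in each gavaged group and do not say whether the RNA of several mice was pooled. The deposited table assigned 27220697 counts to genes in the untreated library, 16289580.0 in the PBS library, 29368008 in the E. coli library and 29899371 in the LGG library. A count of 0 allowed up to 0.105, 0.187, 0.103 and 0.103 CPM (counts scaled to library size) in these libraries. With 1 library per condition, none of the differences has a replicate check, and every interval covers counting error only.

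The title of the series names the Nrf2 pathway, the transcriptional response to oxidants and electrophiles, so the first question was whether this pathway differed in the LGG library. Nfe2l2, which encodes Nrf2 (NM_010902, chromosome 2, 75513576 to 75542698 in mm9), was measured at 208 CPM in the untreated, 202 in the PBS, 202 in the E. coli and 211 in the LGG library. Against PBS, LGG gave log2 ratios of 0.06 (95% counting interval 0.00 to 0.13) for Nfe2l2 and 0.11 (0.01 to 0.22) for Keap1, its inhibitor. Among classical targets, the LGG against PBS ratios were 0.09 for Nqo1, -0.20 for Hmox1, -0.03 for Gclc, 0.13 for Gclm, -0.10 for Txnrd1 and 0.11 for Srxn1. Hmox1 was the least abundant of these genes, at 4.23 to 5.17 CPM, and its interval of -0.60 to 0.22 was correspondingly wide. None of the 45 measured members of the 46-gene Nrf2 list passed the 2-fold size rule in LGG against PBS, in E. coli against PBS or in LGG against E. coli.

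The median log2 ratio of the Nrf2 list was 0.05 (0.02 to 0.08) in LGG against PBS, with 30 of 45 members positive. Random lists matched on expression had a central 95% range of -0.04 to 0.06, which included this median only narrowly. Unrounded, the median was 0.0546 and the upper limit 0.0558, at percentile 97.14 of the random lists. In E. coli against PBS the median was -0.02 (-0.04 to 0.01), also inside the random range of -0.03 to 0.04 but near its lower end, at percentile 3.165. With the untreated library as control the LGG median was 0.13, above its random range of -0.02 to 0.12, and the E. coli median was 0.095, inside its range of -0.01 to 0.11. In LGG against E. coli it was 0.08 (0.04 to 0.10), above the random range of -0.04 to 0.05, and Srxn1 (0.18), Nqo1 (0.16) and Gclm (0.16) were on the higher side while Txnrd1 was at -0.07. In PBS against untreated, a pair of libraries without bacteria, the Nrf2 median was 0.15 (0.11 to 0.19), above its random range of -0.02 to 0.09. There Txnrd1 was at 0.23 and Srxn1 at 0.22, whereas Nqo1 was at -0.29 and Ces1g, a carboxylesterase, was at -1.37 and past the size rule.

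**Figure D1:**
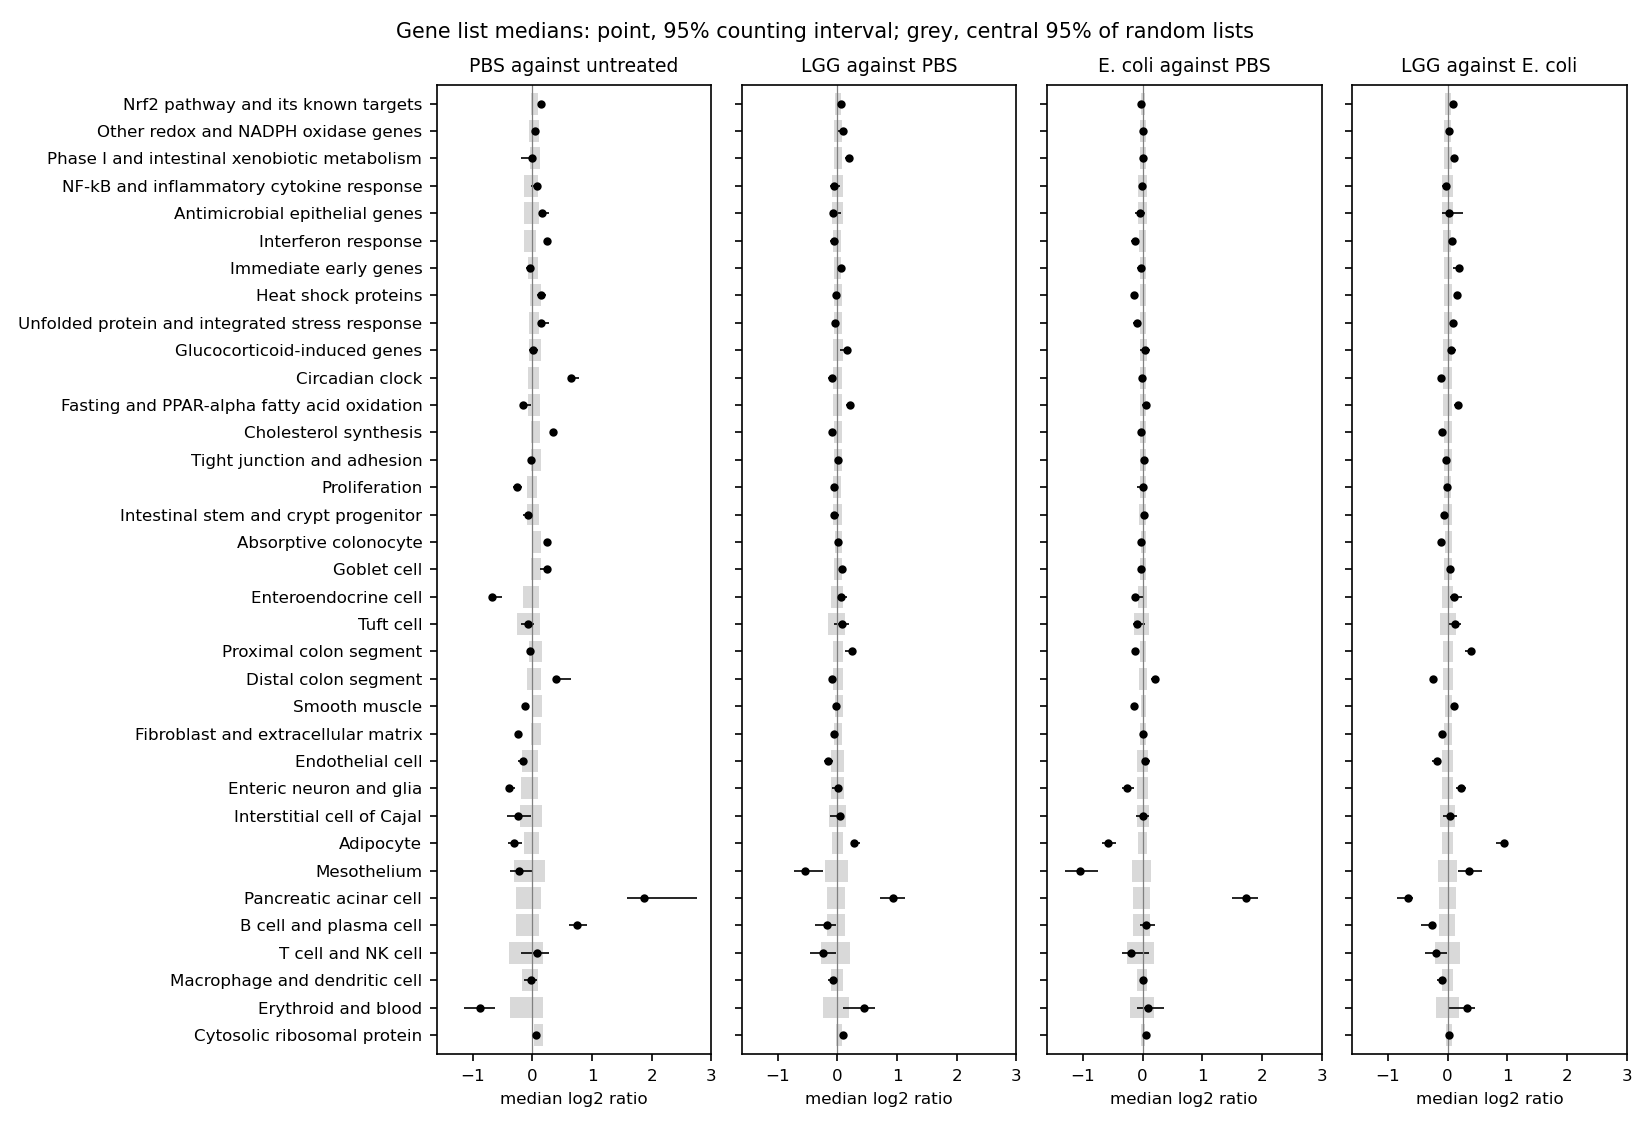
Median log2 ratio of each of the 35 gene lists with at least 5 measured members, in 4 comparisons (x axis, log2 ratio; y axis, list). Points carry 95% counting intervals and grey bars span the central 95% of 10000 random lists matched on expression; the Nrf2 list lies between -0.02 and 0.15, while the pancreatic acinar list reaches 1.88 in PBS against untreated.

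PBS against untreated sets the library gavaged with vehicle beside the library without gavage. An effect of gavage cannot be told here from other differences between the pieces, such as their position along the colon, which was not tested for this pair. Genes of the circadian clock differed together: 8 of 19 measured members were higher and 1 was lower past the size rule, with a list median of 0.65 (0.60 to 0.78; random range -0.07 to 0.11). Per2 was at 139 CPM after PBS and 38.9 in the untreated library, a log2 ratio of 1.84 (1.73 to 1.94), and Ciart (1.45), Bhlhe41 (1.44) and Per3 (1.39) were also higher. Per2 and Per3 are repressors in the clock loop. Nfil3, a repressor of the output genes driven by Dbp, was lower at -1.23, and Arntl, which encodes the clock activator Bmal1, was at -0.94 (-1.14 to -0.75); these genes were singled out after their values were seen. Prdx6, a peroxiredoxin that reduces peroxides, was at 2242 CPM after PBS and 792 in the untreated library.

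Apoa4, Akp3, lactase (Lct), Apoa1 and Prap1 were lower after PBS, while the absorptive colonocyte list as a whole was higher, at a median of 0.24 (0.22 to 0.28) with 16 of 22 members positive. A small intestinal enterocyte list assembled after seeing the data had a median of -0.59 (-0.72 to -0.06 over resampled genes), with 17 of 24 measured members negative, among them Treh (-1.82), Sis (-0.97) and Anpep (-0.96), and 7 positive, among them Rbp2 (0.93). Apoa4, an apolipoprotein secreted with intestinal lipid (NM_007468, chromosome 9, 46048927 to 46051541 in mm9), was at 45.8 CPM in the untreated library and had a log2 ratio of -5.18 (-5.92 to -4.57). Akp3, an intestinal alkaline phosphatase (NM_007432, chromosome 1, 89021583 to 89024487 in mm9), was at -4.65, Lct at -3.88, Apoa1 at -2.09, Prap1 at -1.63 and the bile acid transporter subunit Slc51a at -1.39. In the list of fasting and PPAR-alpha targets, 4 of 21 genes were lower, among them Vnn1 (-1.58), Pdk4 (-1.43), a kinase that restrains glucose oxidation, and Acaa1b (-1.35); the list median was -0.16 (-0.19 to -0.02). All 21 measured cholesterol synthesis genes had positive ratios, with a median of 0.35 (0.31 to 0.37). The xenobiotic-metabolism genes Ugt2b5 (-1.18) and Cyp4b1 (-1.01) and the metallothionein Mt2 (-1.11) were lower, as were Adamts4 (-3.14) and Ugt8a (-2.02).

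Cell type markers also differed between these libraries without bacteria. Genes of pancreatic acinar cells, which make digestive enzymes and are no part of the colon, were higher after PBS in 11 of 16 cases, among them Cpa1 (4.40), Try4 (4.30), Ctrb1 (4.27), Pnlip (4.18), Cel (3.59), Prss2 (3.57) and Cela3b (3.07). The untreated library held 2 counts each of Cpa1, Try4 and Cel, so the interval of Cpa1 ran from 2.76 to 7.85. The B and plasma cell list had a median of 0.75 (0.61 to 0.91), with Derl3 (1.78), Fcer2a (1.37), Mzb1 (1.33) and Cr2 (1.07) past the rule. The enteroendocrine list was lower, at -0.67 (-0.71 to -0.51), with neurotensin (Nts) at -1.22, and so were the erythroid list at -0.88 (-1.14 to -0.62), with Hbb-bs at -1.06 from reads it can share with Hbb-b1, and the enteric neuron and glia list at -0.39 (-0.45 to -0.29), in which none of 18 genes had a positive ratio. The smooth muscle list was at -0.12 (-0.16 to -0.09), below its random range, with 3 of 20 members positive.

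Of the lists for position along the colon, the proximal list had a median of -0.03 (-0.08 to 0.01), inside its random range of -0.05 to 0.15. Of its 15 members, 4 were lower past the rule, namely Apoa4, Apoa1, Hoxb6 (-1.50) and Hoxb7 (-1.26), and 1 was higher. All 14 measured genes of the distal list had positive ratios, with a median of 0.40 (0.38 to 0.65) and the sodium channel subunit Scnn1g at 1.34. Rn45s, the ribosomal RNA precursor, was higher after PBS (2.43), and Lars2 had a log2 ratio of 2.30 (2.27 to 2.33) while Chrdl2 was at 2.13. Altogether 209 of 14450 genes were past the size rule in PBS against untreated, 96 higher and 113 lower. With library totals in place of TMM scaling the split was 73 higher and 156 lower.

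**Figure D2:**
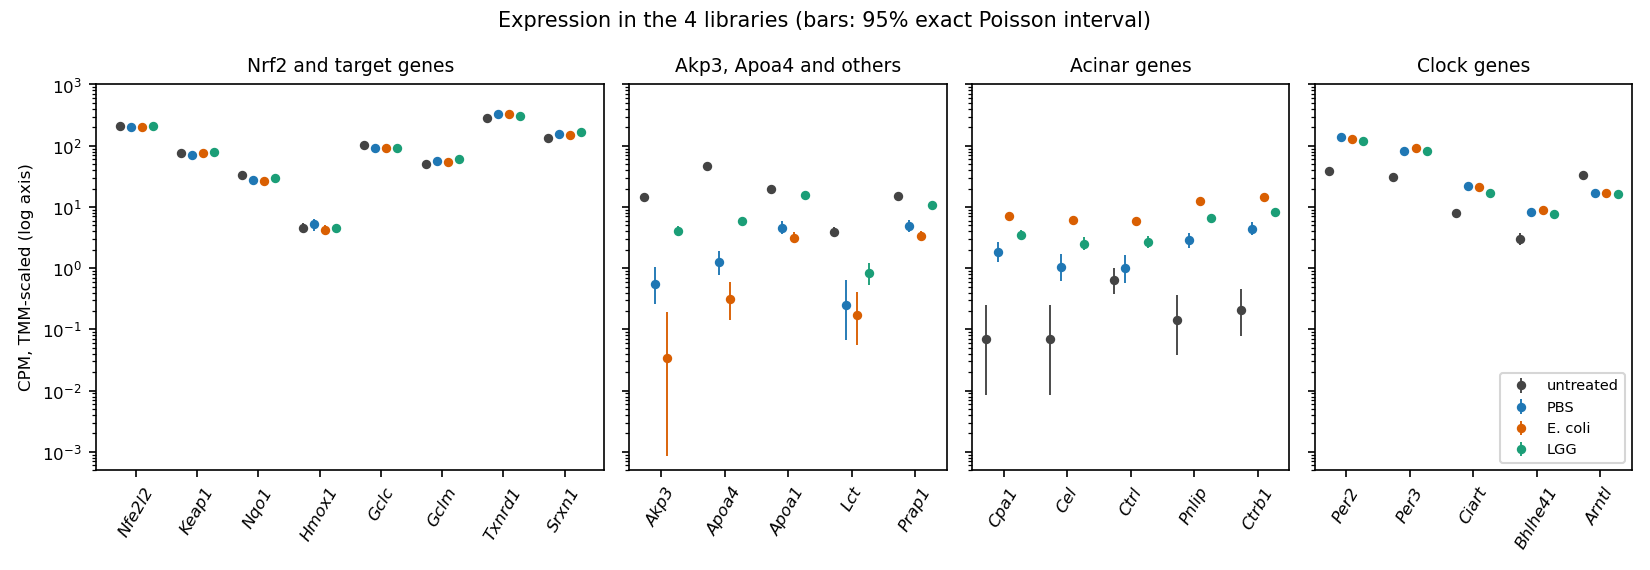
Expression of 8 Nrf2 pathway genes, 5 genes led by Akp3 and Apoa4, 5 pancreatic acinar genes and 5 clock genes in the 4 libraries (y axis, TMM-scaled CPM on a log axis; x axis, gene). Points are single libraries with 95% exact Poisson intervals; Nfe2l2 lies between 202 and 211 CPM throughout, while Apoa4 runs from 0.310 CPM in the E. coli library to 45.8 in the untreated library.

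LGG against PBS is the comparison of the probiotic with its vehicle. In this pair, 40 genes were past the size rule, 26 higher and 14 lower, fewer than the 209 between the libraries without bacteria. Past the rule, 12 genes were higher after LGG than after PBS and lower after PBS than in the untreated library, where counting noise around the shared PBS library gave a mean of 3.12 and at most 7 in 100 simulations. Among the 12 were Akp3 at 2.80 (1.87 to 4.01), Apoa4 at 2.24 (1.58 to 3.0), Apoa1 at 1.75 (1.39 to 2.13), Lct at 1.64 (0.18 to 3.71) and Prap1 at 1.14 (0.78 to 1.52). Each of these named genes was still lower after LGG than in the untreated library, by log2 ratios of -1.85 for Akp3, -2.94 for Apoa4, -0.34 for Apoa1, -2.23 for Lct and -0.49 for Prap1. Akp3, Lct and Prap1 were singled out here after their values were seen. The absorptive colonocyte list had a median of 0.02 (-0.01 to 0.05) in LGG against PBS, inside its random range of -0.04 to 0.08, with 11 of 22 members positive, and the small intestinal list had 19 of 24 members positive and a median of 0.22 (0.02 to 0.30 over resampled genes).

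Among the genes higher after LGG than in both libraries without bacteria, 8 passed the rule. Of these, 6 were pancreatic acinar genes, namely Ctrl (1.42), Pnliprp1 (1.31), Cel (1.24), Pnlip (1.20), Rnase1 (1.14) and Cela2a (1.10), and the others were a carboxylesterase pseudogene and an unnamed transcript. On the lower side 4 genes passed against both, namely Efhb (-1.45), the cadherin Cdh6 (-1.31), the mesothelial gene Lrrn4 (-1.27) and Scrn1 (-1.08). All of these were of low abundance, with Pnlip at 6.60 and Lrrn4 at 1.64 CPM in the LGG library. When the mean CPM had to be at least 5, 6 genes were past the rule, all higher after LGG: Apoa4, Apoa1, Pnlip, Prap1, Cela2a and Scand1, the last chosen after its values were seen.

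Smaller shifts ran through several lists. In the fasting and PPAR-alpha list, 19 of 21 genes had positive ratios after LGG, with a median of 0.21 (0.15 to 0.28; random range -0.07 to 0.08) and no gene past the rule; Ucp2 was at -0.03. Xenobiotic metabolism had a median of 0.19 (0.13 to 0.25), with Abcb1a at 0.12, and glucocorticoid-induced genes 0.16 (0.04 to 0.20), with Sgk1 at 0.21. The NF-kB and cytokine list, at -0.06 (-0.12 to 0.04), the antimicrobial list, at -0.07 (-0.13 to 0.06), and the tight junction list, at 0.00 (-0.02 to 0.06) and below 0 with library totals or upper-quartile factors, lay inside their random ranges, and Cdh1 was at -0.05. Beside these, the proximal colon list was at 0.25 (0.13 to 0.31), the distal list at -0.09, the adipocyte list at 0.28 (0.23 to 0.38) and the mesothelium list at -0.54 (-0.73 to -0.24). Other cell type lists outside their random ranges included the erythroid list at 0.44 (0.10 to 0.62), the B and plasma cell list at -0.18 and the endothelial list at -0.16. Several of these medians depended on the PBS library: with the untreated library as control, LGG gave -0.0084 for xenobiotic metabolism, -0.0034 for glucocorticoid-induced genes, 0.12 for the fasting list and 0.05 for adipocytes, all inside their random ranges, and 0.45 for the distal and 0.27 for the antimicrobial list.

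E. coli against PBS sets the library of the other bacterium against the same vehicle library. The genes highest after E. coli were again those of pancreatic acinar cells, of which 12 of 16 passed the rule: Ctrl at 2.53 (1.81 to 3.39), Cel at 2.49 (1.80 to 3.33), Pnlip at 2.14 (1.70 to 2.62), Cpa1 at 1.91, Cpb1 at 1.87, Prss2 at 1.74, Cela2a at 1.73, Ctrb1 at 1.70 and Try4 at 1.61, with Pnliprp1 3.88-fold higher. Pnlip reached 12.7 CPM, against 6.60 in the LGG, 2.87 in the PBS and 0.140 in the untreated library. Mesothelial genes were lower, with 6 of 9 past the rule and a median of -1.05 (-1.30 to -0.74), including Wt1 (-1.36), Lrrn4 (-1.32), Msln (-1.31) and Upk3b (-1.30). Adipocyte genes were lower as well, at a median of -0.58 (-0.69 to -0.44), with leptin (Lep, -1.52), perilipin 1 (Plin1, -1.35) and adipsin (Cfd, -1.03) past the rule.

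Apoa4 was lower after E. coli than after PBS (-1.94, -3.33 to -0.81), as was Akp3, at -3.43 with an interval of -9.48 to -1.17 from 1 count against 9. Myrf (-1.78), Xlr3b (-1.71) and the calcium-binding protein S100g, which was 2.37-fold lower, were also lower than in both libraries without bacteria. Heat shock genes had a median of -0.14 (-0.19 to -0.10), with Hspa8 at -0.23, and unfolded protein response genes -0.10 (-0.16 to -0.06), with Hspa5 at -0.35. The interferon list was at -0.12 (-0.20 to -0.06), with Irf7 at -0.41 (-0.50 to -0.31), the enteric neuron list at -0.26 (-0.34 to -0.14) and the smooth muscle list at -0.14 (-0.15 to -0.12), with 1 of 20 muscle genes positive. With the untreated library as control the interferon list was at 0.15, above its random range of -0.13 to 0.06. The unfolded protein response list was at 0.09 there, so the directions of these lists depended on the PBS library. The heat shock list kept its sign with that control, at -0.01, but lay inside its random range of -0.04 to 0.15. The NF-kB and cytokine list was at -0.02 (-0.05 to 0.06) and the antimicrobial list at -0.05 (-0.13 to 0.04), both inside their random ranges, and among immediate early genes Nr4a3 alone was past the rule, at -1.22 (-2.09 to -0.41). Alox15, an eosinophil and mast cell list member, was at -1.47 (-2.14 to -0.84).

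Altogether 60 genes were past the rule in E. coli against PBS, 25 higher and 35 lower, and 21 of them belonged to the acinar, adipocyte, mesothelium or blood lists. Without the genes of those lists 39 were left, 13 higher and 26 lower, a count chosen after seeing the data. The distal colon list had a median of 0.20 (0.14 to 0.24) and the proximal list -0.12 (-0.17 to -0.10). Rn45s (-1.15) and Lars2 (-1.14) were lower after E. coli, both singled out after their values were seen.

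LGG against E. coli sets the bacteria side by side without the PBS library. Akp3 had the highest ratio, at 6.23 with an interval of 4.37 to 12.19 from 118 counts against 1, followed by Apoa4 at 4.18 (3.30 to 5.42), Apoa1 at 2.29 (1.97 to 2.63) and Lep at 2.23 (1.33 to 3.37). Adipocyte genes were higher after LGG, with 7 of 16 past the rule and a median of 0.94 (0.81 to 1.02), among them Plin1 (1.90), Cidec (1.32) and Cfd (1.32). Hp (1.68), Prap1 (1.66) and S100g (1.65) were higher too, and the antimicrobial lectin Reg3g was at 1.04 (0.44 to 1.69), with 2.43 CPM after LGG, 1.17 after E. coli and 3.05 in the untreated library. On the lower side were the acinar genes Cel (2.39-fold), Ctrl (-1.11) and Cpa1 (-1.02), the Toll-like receptor homologue Cd180 (-1.36), the macrophage lectin Siglec1 (-1.13), Sstr3 (-1.35), Vtcn1 (-1.24), Rims4 (2.00-fold) and the tight junction gene Cldn1 (-1.03).

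Positional genes differed in the same pair: Hoxd13 was at -1.34 (-1.50 to -1.18) and Hoxd12 at -1.26, both of the distal list, whereas Hoxb6 of the proximal list was at 1.10 (0.87 to 1.33). The proximal list had a median of 0.40 (0.29 to 0.44) and the distal list -0.24 (-0.29 to -0.21). Apoa4 and Apoa1 are members of the proximal list, so its median is not separate evidence on where those genes come from. Heat shock genes were at 0.15 (0.11 to 0.18), immediate early genes at 0.18 (0.09 to 0.22), enteric neuron genes at 0.22 (0.13 to 0.31), smooth muscle genes at 0.11 (0.09 to 0.13) and fasting and PPAR-alpha genes at 0.17 (0.11 to 0.22), each above its random range with no member past the rule. B and plasma cell genes were at -0.27 (-0.44 to -0.19). In all, 52 genes were past the rule, 38 higher and 14 lower after LGG.

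**Figure D3:**
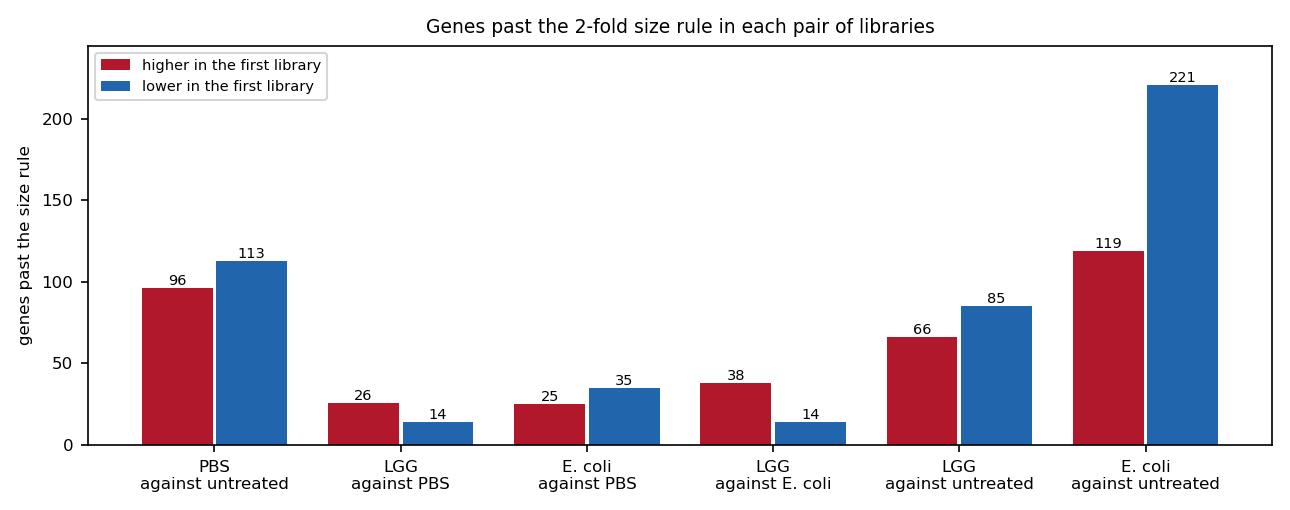
Number of genes past the 2-fold size rule in each of 6 pairs of libraries (y axis, genes; x axis, pair), higher (red) or lower (blue) in the library named first. The 3 pairs that include the untreated library hold 209, 151 and 340 genes, against 40, 60 and 52 in the other pairs.

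Genes past the rule in both bacterial libraries were counted next. Against PBS, 8 genes were higher in both bacterial libraries and 2 lower in both. Counting noise around a shared PBS library gave a mean of 3.05 shared higher genes and 0.24 shared lower genes in 100 simulations, with up to 10 and 1. The number of shared higher genes was within that range and the number of shared lower genes was above it. Intervals of shared genes, such as Pnlip (0.73 to 1.70 in LGG, 1.70 to 2.62 in E. coli), exclude 0 because the rule requires it. They also use the same PBS count, so they add no support. Lists with no library in common would share 0.0450 and 0.0339 genes. Akp3 and Apoa4 were past the rule in opposite directions. At a mean CPM of at least 1, 7 genes were at least 2-fold apart between both bacterial libraries and both libraries without bacteria: Pnlip, Cel, Pnliprp1, Cela2a, Ctrl and Rnase1, all acinar, were higher and Lrrn4, a mesothelial gene, was lower. Without that filter there were 252 such genes, and 2 at a mean CPM of at least 5. The other partings of the 4 libraries into pairs gave 5 genes (Akp3, Apoa4, Apoa1, Lct and Prap1, higher in the untreated and LGG libraries) and 2 genes (Rn45s and Vaultrc5, lower in the untreated and E. coli libraries). These genes were named after their values were seen.

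Across the 14450 genes, which are not independent replicates, the LGG and E. coli log2 ratios against PBS had a Pearson r of 0.441 and a covariance of 0.0206. Counting noise around a shared PBS library alone gave 0.649 and 0.0161 in simulations. The observed r was below the simulated r and the observed covariance somewhat above the simulated one. The r of 0.441 is therefore no evidence of a response shared by the bacteria. With separate controls r was -0.0708 when E. coli was set against the untreated library and 0.269 when LGG was.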

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

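No test on Hox or small intestinal genes was chosen after its result was seen, although the pattern they address was found in the same data.

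Akp3 and Apoa4 stood out because they were past the size rule against PBS in opposite directions in the bacterial libraries, a difference between groups that was not tested for lack of replicates. The LGG against E. coli log2 ratio was 6.23 for Akp3 (4.37 to 12.19) and 4.18 for Apoa4 (3.30 to 5.42). Akp3 had 416 counts in the untreated library, 9 in PBS, 1 in E. coli and 118 in LGG, and Apoa4 had 1308, 20, 9 and 174.

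A candidate explanation for Akp3, Apoa4 and Apoa1 is that the LGG piece came from a more proximal part of the colon. On 11 anterior and 5 posterior Hox genes not looked at before, the anterior minus the posterior median was 0.018 in LGG against E. coli (-0.48 to 0.51 over resampled genes). In LGG against PBS it was -0.11 (-0.23 to 0.06), so neither difference was told from 0. The 5 posterior genes were Hoxa9, Hoxa10, Hoxa11, Hoxb9 and Hoxd9. The most posterior groups, to which Hoxd12 and Hoxd13 belong, had no gene in the test, so a difference confined to them could not be seen. Hoxb6 (1.10) and Hoxd13 (-1.34), whose values prompted the test, do part in the direction of a more proximal LGG piece. Small intestinal tissue in the LGG library was tested on 6 small intestinal genes under 1 CPM in the E. coli library, whose median was 0.86 (-0.42 to 1.77). The highest and the lowest of the 6, Slc2a2 (2.06) and Cyp3a25 (-1.47), were both at 0.0344 CPM in the E. coli library. That is under the 0.103 CPM that a count of 0 allows there, so the ends of this range rest on genes near the floor. Choosing genes low in the E. coli library favours a positive ratio, and all 24 measured genes of the list had a median of 0.19 (-0.02 to 0.36) with 16 positive, so this too stayed open. An effect of LGG remains open and untested, and the untreated library, which received no bacteria, held more Akp3 and Apoa4 than the LGG library.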

How the results depend on the processing

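The alternatives without Rn45s and without genes of other tissues were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The choice of the longest transcript was not run, since each gene has 1 row. Of 2251 named gene values under other scalings, filters and the prior of 5, 2201 stayed inside the counting interval and none that was past the size rule changed sign. Of 880 values for the other lists under the same settings, 837 stayed inside the counting interval. The untreated library as control, which turned several list medians, is not among these settings. Total counts past the rule stayed within 1.5 times under every other scaling, the prior of 5 and TMM without Rn45s, but with the prior of 5 the lower genes of LGG against E. coli went from 14 to 8 and the higher genes of E. coli against PBS from 25 to 16.

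Counts past the rule, given for PBS against untreated, LGG against PBS, E. coli against PBS and LGG against E. coli, were 358, 106, 135 and 162 with no filter, 85, 6, 10 and 13 at a mean CPM of at least 5, and 855, 227, 212 and 316 at 1.5-fold, since these settings change how many genes can pass. With the untreated library as control they were 151 for LGG and 340 for E. coli. Leaving out genes of other tissues gave 39 for E. coli against PBS and stayed within 1.5 times in the other comparisons. Genes parting both bacterial libraries from the rest numbered 252 with no filter, which admits genes near the floor, and 2 at a mean CPM of at least 5.

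Library totals change 1 factor per library, which lowered the median of all genes in PBS against untreated by 0.0898. This gave a Nrf2 median of 0.061 there, and turned the sign of the other redox list (-0.037) and the ribosomal protein list (-0.028) by the same shift. The Nrf2 median was 0.13 for LGG and 0.095 for E. coli with the untreated library as control. The correlation was -0.0708 and 0.269 with separate controls, 0.598 with no filter and 0.373 at a mean CPM of at least 5. Among named genes past the size rule against PBS, signs turned with the untreated library as control for 5 genes in LGG. These were Akp3 (-1.85), Apoa4 (-2.94), Apoa1 (-0.34), Lct (-2.23) and Prap1 (-0.49). In E. coli, Rn45s (1.28) and Lars2 (1.16) turned. Ratios short of the rule turned as well, such as Prdx6 in LGG, from -0.43 to 1.07. Several list medians turned with that control too. In LGG these included xenobiotic metabolism (-0.0084), glucocorticoid-induced genes (-0.0034), the antimicrobial list (0.27) and the distal list (0.45). Larger turns in LGG included the erythroid (0.44 to -0.48), clock (-0.09 to 0.63) and B and plasma cell (-0.18 to 0.55) lists. In E. coli the turned medians included the interferon (0.15), unfolded protein response (0.09), erythroid (-0.78), clock (0.68), cholesterol synthesis (0.34) and Nrf2 (0.095) lists. In PBS against untreated the antimicrobial list (-0.0056) and the eosinophil and mast cell list (-0.14) turned with no filter; the last was at 0.19 with no filter in E. coli against PBS. Without the filter, more genes enter a list; the cause was not tested further. The PBS library, with 16289580.0 counts, sets the precision of the comparisons that use it.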

Other observations

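The tests on acinar, clock and glucocorticoid-induced genes were chosen after their results were seen, and their criteria were changed after that, which moved the acinar and clock tests from in favour to undecided and the glucocorticoid test from excluded to undecided. Both bacterial libraries were also set against the untreated library. LGG gave 151 genes past the size rule and E. coli 340, of which 221 were lower. Eln, the elastin gene, and Lox, which cross-links elastin and collagen, were highest in the untreated library. Eln was at 103 CPM there, 51.4 after PBS, 50.1 after E. coli and 42.9 after LGG, and Lox had a log2 ratio of -1.33 (-1.69 to -0.98) in PBS against untreated. Upp1, a uridine phosphorylase, was lowest in the untreated library, at 26.6 CPM, against 71.5 after PBS, 75.9 after E. coli and 58.0 after LGG. These genes were picked after their values were seen. Relative to each of the other 3 libraries, 28 genes were higher and 46 lower in the untreated library, 1 and 1 in the PBS library, 3 and 9 in the E. coli library and 2 and 1 in the LGG library.

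Over 27 measured Hox genes, the deviation from the mean of the 4 libraries, groups up to 8 minus groups from 9, was 0.80 in the untreated, -0.10 in the PBS, -0.72 in the E. coli and 0.00 in the LGG library. These include Hoxb6 and Hoxd13, which prompted the question. The Hox genes not looked at before were tested only in LGG against E. coli (0.018) and in LGG against PBS (-0.11). From highest to lowest the Hox value ran from untreated through LGG and PBS to E. coli, with LGG and PBS close together. Akp3, Apoa4, Apoa1, Lct and Prap1 had the same order of libraries by CPM, which was seen afterwards and not tested. Among non-coding RNAs, Rmrp was at 1.05 CPM in the untreated, 3.86 in the PBS, 2.20 in the E. coli and 6.63 in the LGG library, and Rpph1 at 2.17, 7.60, 4.20 and 9.23. Xist was at 573 to 627 CPM in the 4 libraries, and Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each.

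For the acinar genes, 1 source of pancreatic RNA present in differing amounts was tested. Such a source would move its genes by 1 ratio, and the SD of the LGG against E. coli log2 ratio over the 12 genes past the rule in E. coli against PBS was 0.213, beside 0.181 from counting error. These genes were kept because they were higher after E. coli, so a small spread was largely set by the choice and decides nothing. Over all 16 measured list members the SD was 0.370. This wider SD mixes genes that rose with members that did not, such as Clps, so it does not decide either. Clps, which encodes an abundant pancreatic colipase and was singled out after its values were seen, was at 7.57 CPM in the untreated, 7.85 in the PBS, 7.92 in the E. coli and 8.68 in the LGG library. Carried-over pancreatic tissue and a joint induction by gavage or bacteria both stay open.

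For the clock genes in PBS against untreated, another time of day at collection was tested. The Per, Rev-erb and Dbp side minus the Bmal1 and Clock side gave 2.27 (0.74 to 2.58 over resampled genes). This restates the pattern on the genes that showed it, so it decides nothing and another phase of the clock stays open. Nr1d1 (-0.41), grouped on the Per side, and Cry1 (0.57), grouped on the Bmal1 side, differed in sign from the median of their side. The grouping sets no time of peak for single genes, so these signs do not argue against another phase. The list of glucocorticoid-induced genes fixed beforehand had a median of 0.015 (-0.05 to 0.09), inside its random range, with 8 of 15 members positive. The test used 10 of its genes outside the clock and left out others outside the clock, such as Pdk4 (-1.43). These 10 genes had a median of 0.10 (-0.14 to 0.30), not told from 0, beside a clock list median of 0.653. Their SD of 0.464 is a spread between genes, and these lists need not move by the same amount. Glucocorticoid induction therefore stays open. An effect of gavage on the clock stays open and untested.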
